A study of Mus musculus with 8 samples.

How the data were processed

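Gene expression was measured in 8 spontaneous mammary tumours of neu-transgenic mice on Illumina bead arrays with biotin-labelled cRNA, per the labels' protocols. The labels put 4 tumours in the control cream group and 4 in the imiquimod group, and this mapping alone set the groups. They do not say whether the 4 tumours of a group came from separate animals, so p-values measure only the spread between these samples, which may be partly technical.

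The values used were the log2 signals of the deposited series table, with 1 column for each sample. By the values themselves, the authors deposited log2 signals with nearly equal distributions on all 8 arrays, as after quantile normalization. Array medians lay between 6.816 and 6.824 and the highest value was 14.86 on each control array and 15.07 on each imiquimod array. The sources used here do not explain why the highest value differed between the groups. A processing step applied to each group apart is therefore not excluded, and it could not be told apart from treatment. The submitters' processing notes name the R package affy with no version and no role. Background correction, its settings and detection calls are not given in the sources used here. Whether a background was subtracted is unknown, and if it was not, fold changes of dim genes would understate their change. The number of arrays limits the precision.

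The design fixed beforehand was to start from the non-normalized signals. Their 16 columns of per-sample values carry running numbers that match no label of a sample, so they were not used here, and the test was run on the deposited log2 values without a further background or normalization step, as the fixed design provides for that case. Only the probe accessions and symbols of that table were used, to name probes. Of 24341 probes, 20038 were named through an unversioned accession, 1620 through a current symbol and 1736 through a synonym in a table of mouse RefSeq genes. Another 690 kept the symbol of the file and 257 had no name. The files name no genome build, so no coordinates are given.

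The third of probes with the lowest mean over all 8 arrays was left out, which removed probes under a mean log2 signal of 6.64 and kept 16228. Each gene was represented by its probe with the highest mean, giving 13143 units, of which 13005 were named genes and 138 unnamed probes. Imiquimod was compared with control using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), and Benjamini-Hochberg adjusted p below 0.05 over all 13143 units was the threshold. Every fold change is imiquimod minus control on the log2 scale, with its standard error (SE) from that model. Of 136 changed genes with several kept probes, 19 had a probe of the other sign, the smallest unadjusted p of such a probe being 0.0376 (Fosl2). No 2 arrays held identical values.

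A set of 32 gene lists was fixed before the data were examined, covering immune responses, the cell types a mammary tumour or the skin over it could hold, and metabolic and growth programmes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Fry tests whether the genes of a list move 1 way on balance and does not compare them with other genes. A score per tumour, the mean log2 difference from the control mean over a list, was compared with an exact permutation test, two-sided, whose smallest possible p with 4 against 4 is 0.0286. The genes named are, by a rule fixed beforehand, the 12 with the highest and the 12 with the lowest log2 fold change among those past the threshold with no overlap between the groups, the 4 members of each list with the smallest p, and Tlr7, Il10 and Erbb2 whatever their result. Some genes that the rule names, and 1 gene family, are not reported here. Any other gene named was chosen after its values were seen.

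The procedure was tested on simulated data with the same 13143 units and group sizes. Of 50 genes changed by a log2 difference of 0.5, 23 were recovered (46%), and of 50 changed by 1, 44 were recovered (88%). At a log2 difference of 2 the number was 49 of 50 (98%), and at 3 it was 50 of 50 (100%). Of 173 calls, 7 were false. The 1 list shifted by 0.5 was called and none of the unshifted lists was. The simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.676 (fibroblast and matrix genes). The simulation therefore cannot show how often camera at the preset correlation calls correlated lists falsely.

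Alternatives covered the normalization between arrays, the filter on dim probes, the variance model, array weights, the probe of a gene, the replicate number as a block, the threshold, the list test and each tumour left out in turn. Added after seeing the data were a normexp background correction with an offset of 50 or 16, a repeated quantile normalization, and imiquimod tumours 3 and 4 left out together because they carried the most skeletal muscle signal. All alternatives started from the deposited values, so those on normalization could not test the authors' own normalization. Samples were also checked for values far from the rest of their group with Dixon's test, whose critical value for 4 samples is 0.829. Figures were drawn with matplotlib 3.10.9.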

Results

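Total RNA from 8 spontaneous mammary tumours was profiled, 4 from mice given topical imiquimod for 1 cycle and 4 from mice given control cream. The mice were neu-transgenic mice of the FVB/N background, in which the neu oncogene is expressed from a mammary tumour virus promoter and mammary tumours arise. Imiquimod is a synthetic agonist of the innate immune receptor TLR7. The comparison asks how gene expression in treated tumours differed from that in control tumours. Correlations between arrays averaged 0.9641 to 0.976 with the other arrays of the group and 0.9373 to 0.9642 with arrays of the other group. The first principal component held 43% of the variance and placed the control tumours between -27.2 and -18.1 and the imiquimod tumours between 5.04 and 33.8.

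In imiquimod tumours 10 of 30 chemokine and receptor genes, 19 of 23 interferon-stimulated genes and 10 of 23 macrophage and monocyte markers rose, and 18 of 26 proliferation genes fell. As lists, the chemokines held with an estimated correlation (adjusted p = 0.0411) and the other 3 did not (adjusted p = 0.112, 0.138 and 0.0608 with an estimated correlation). Fry, which does not compare a list with other genes, passed the chemokines (adjusted p = 0.000531). It also passed the other 3 (fry adjusted p = 0.00583, 0.00915 and 0.000531). The chemokine Ccl4, which attracts monocytes and T cells, rose most, from a log2 signal of 6.90 ± 0.12 to 11.61 ± 0.88 (mean ± SD, n = 4 each). This was a log2 fold change of 4.70 (SE 0.37, adjusted p = 0.000816), and a second Ccl4 probe gave 2.77. Among the genes that fell most was Cenpa, the histone variant of the centromere, by 1.78 on the log2 scale (SE 0.24, adjusted p = 0.0054). Of 13143 genes and unnamed probes tested, 569 passed the threshold, 280 higher and 289 lower with imiquimod. At least a 2-fold difference was reached by 125 of the higher and 51 of the lower ones. In 1659 (12.6%) the groups did not overlap, against 2.86% by chance.

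**Figure D1:**
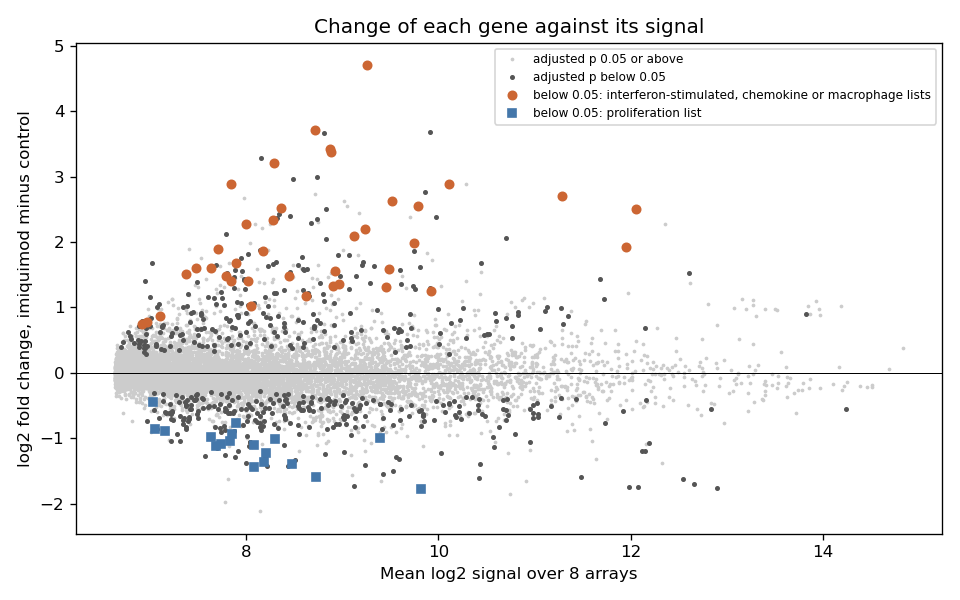
Log2 fold change of each gene, imiquimod minus control (y axis), against its mean log2 signal over 8 arrays (x axis), with genes past the threshold in dark or in colour. Higher genes reach 4.70 (Ccl4) and lower genes past the threshold reach -1.78 (Cenpa).

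Of 30 chemokine and chemokine receptor genes tested, 10 rose and none fell (15 higher when adjusted over the list alone), with a mean log2 difference of 1.10 (camera adjusted p = 2.21e-10). This was the single list whose call held with an estimated correlation (adjusted p = 0.0411). Ccl7 and Ccl12, monocyte attractants, rose by 3.71 (SE 0.27) and 3.38 (SE 0.26), and Ccl3 rose by 3.21 (SE 0.34), with adjusted p between 0.000816 and 0.00279. Of 23 macrophage and monocyte markers, 10 rose and none fell (12 higher adjusted over the list alone), with a mean of 0.86 (camera adjusted p = 5.49e-10). That call was lost with an estimated correlation (adjusted p = 0.138 with an estimated correlation). Csf1r (0.06), Lyz2 (0.21) and Msr1 (0.03), macrophage markers chosen after their values were seen, did not pass. Those that rose included Fcgr4, an activating receptor for IgG (log2 fold change 3.43, SE 0.31), the endotoxin co-receptor Cd14 (2.55, SE 0.32), the complement component C1qb (1.36, SE 0.18) and Aif1 (1.56, SE 0.23, with 0.40 on a second probe). Of 21 complement and acute phase genes, 10 rose and none fell (14 adjusted over the list alone), with a mean of 1.33 (camera adjusted p = 2.09e-13; adjusted p = 0.0608 with an estimated correlation). Scores in imiquimod 1 to 4 were 0.82, 1.49, 1.74 and 1.28 for complement genes, 0.63, 0.56, 1.23 and 1.03 for macrophage markers and -0.09, 0.88, 1.64 and 0.87 for fibroblast and matrix genes. Skeletal muscle markers were high in imiquimod 3 and 4 alone (1.60 and 1.32). Complement factor B (Cfb) rose by 2.36 and properdin (Cfp) by 2.04. C4a and C4b, which are near-identical copies that a probe may not tell apart, rose by 2.77 and 1.63, and the other probes of C4b gave 0.12 to 1.23. Saa3, an acute phase protein, rose by 3.66 (SE 0.69, adjusted p = 0.0229), but its imiquimod values spread with an SD of 1.67. Its adjusted p reached 0.0664 with a tumour left out, and the call was lost without control 1, 3 or 4 or imiquimod 2, 3 or 4. Tgfbi, a matrix protein, rose by 3.00 (SE 0.23; 1.95 on a second probe), and Ly6a, a surface protein that interferon induces, by 3.68 (SE 0.48).

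Of 17 neutrophil markers, 1 rose and none fell (2 higher adjusted over the list alone), with a mean of 0.59 (camera adjusted p = 0.00292; adjusted p = 0.154 with an estimated correlation). The member that rose was Fpr2, a formyl peptide receptor that macrophages carry too (3.28, SE 0.25). S100a8 had a log2 fold change of 1.76 that did not pass (adjusted p = 0.0654; 0.0216 to 0.145 over 20 alternatives, of which 4 passed). Ltf, which also stands in the list of milk genes, had 2.89 with an SE of 1.03 (adjusted p = 0.149). Its log2 signal was 14.76 in imiquimod 2, the tumour with the highest milk score (2.18), and its log2 fold change was 1.88 without that tumour (adjusted p = 0.209) and 3.83 without imiquimod 1 (adjusted p = 0.028).

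Genes induced by interferons were higher in all 4 imiquimod tumours. Of 23 interferon-stimulated genes, 19 rose and none fell (22 adjusted over the list alone), with a mean of 1.66 (camera adjusted p = 8.95e-22; adjusted p = 0.112 with an estimated correlation). The scores per tumour lay between 1.26 and 1.93 with imiquimod and between -0.43 and 0.72 in controls, the highest control being control 1 (exact permutation test, p = 0.0286, the smallest possible). Isg15, a ubiquitin-like modifier, rose by 2.88 (SE 0.49), Ifit3 by 2.52 (SE 0.33; 2.75 and 0.29 on its other probes) and Mx2, an antiviral GTPase, by 1.67 (SE 0.27). Oas2, an activator of RNA degradation, rose by 2.89 (SE 0.49, adjusted p = 0.0164), with an adjusted p of 0.0507 without control 4. Of 21 genes induced by interferon gamma, 10 rose and none fell (12 adjusted over the list alone), with a mean of 0.92 (camera adjusted p = 2.28e-12; adjusted p = 0.11 with an estimated correlation). Of these 21, 7 also stand in another list. The guanylate binding proteins Gbp3 and Gbp7 rose by 2.39 and 1.14, and Irgm1 by 1.48. Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.56 (SE 0.11, adjusted p = 0.000816).

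Of 25 genes of MHC class I and antigen processing, 3 rose and none fell (8 adjusted over the list alone), with a mean of 0.61 (camera adjusted p = 4.37e-07; adjusted p = 0.278 with an estimated correlation; 0.0879 with fry). Scores in imiquimod 1 to 4 were 0.98, 0.56, 0.27 and 0.64, and that of control 1 was 0.61, within their range (exact permutation test, p = 0.0857). The genes that rose were the peptide transporter Tap2 (0.79), the immunoproteasome subunit Psmb10 (1.33) and the proteasome activator Psme1 (0.74). Psmb10 had an adjusted p of 0.0508 without control 3. Psme1 lost its call without any control or without imiquimod 2 or 4 (adjusted p up to 0.0829). None of 11 MHC class II genes passed, whose mean was 0.11 and median -0.02 (camera adjusted p = 0.631). Cd74 and H2-Ab1 had log2 fold changes of 0.90 (adjusted p = 0.161) and 0.68 (adjusted p = 0.339). The other members ranged from -0.39 to 0.51, and several of them were dim, with control means down to 6.775, so a flat mean says little of those. Of 26 genes of the Toll-like receptor pathway, 5 rose and none fell (10 adjusted over the list alone), with a mean of 0.43 (camera adjusted p = 4.37e-07; adjusted p = 0.112 with an estimated correlation). Tlr2 rose by 1.21 and the transcription factors Irf7 and Irf5 by 2.63 and 0.58. Tlr7 itself, the receptor of imiquimod, had a log2 fold change of 0.36 (SE 0.13) that did not pass (adjusted p = 0.168). Its mean was 6.48 in controls and 6.84 with imiquimod, near the filter limit of 6.64, so this says little of the receptor.

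Of 23 inflammatory cytokine and NF-kB target genes, 4 rose and none fell (11 higher and 1 lower adjusted over the list alone), with a mean of 0.32 (camera adjusted p = 2.3e-06; adjusted p = 0.0608 with an estimated correlation). Icam1, an adhesion molecule for leukocytes, rose by 1.23 (SE 0.10) and Nfkbiz by 0.85. Tnf rose by 0.56 (adjusted p = 0.0203), but its adjusted p reached 0.0569 without control 1 or 4 or imiquimod 4 in turn. Of 26 genes of immune regulation and the Il10 axis, 4 rose and none fell (9 adjusted over the list alone), with a mean of 0.23 (camera adjusted p = 0.000252; adjusted p = 0.0701 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.43 (SE 0.31). Il10 had a log2 fold change of 0.58 (SE 0.15) that did not pass (adjusted p = 0.0626; 0.0275 to 0.133 over 20 alternatives, of which 3 passed), with 7.72 in imiquimod 4 and 7.05 to 7.09 in the other imiquimod tumours.

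No marker of T cells passed among 17 tested, with a mean of -0.01 (camera adjusted p = 0.901). Cd3e had a log2 fold change of 0.14 (adjusted p = 0.559). The control means of Cd3e and Cd3g were 6.85 and 6.76, near the array medians, so their flat values say little of T cells. Of 14 NK and cytotoxic cell markers, 1 rose, both over all genes and adjusted over the list alone. That member was the chemokine Ccl5 (2.28, SE 0.38), which many cell types make, while Nkg7 had 0.48 (adjusted p = 0.182), and 0.31 without imiquimod 4. The NK list had a camera adjusted p of 0.0127 (adjusted p = 0.287 with an estimated correlation), and 0.0804 without imiquimod 4. Of 14 B and plasma cell markers, 2 rose (also 2 adjusted over the list alone), namely Cd72, a coreceptor of B cells (2.97, SE 0.29), and the immunoglobulin heavy chain Ighm (1.04, SE 0.15). The B cell list did not pass (camera adjusted p = 0.0504), and left out in turn, control 1, 3 or 4 or imiquimod 2 or 4 brought it to between 0.0192 and 0.0493. It passed in 13 of 22 alternatives in all, among them several that kept all tumours, such as the stricter filter on dim probes (0.0268), the intensity trend (0.0413) and fry (0.0304). Of 19 dendritic cell markers, 1 rose, also adjusted over the list alone. It was Itgax (0.62), an integrin that macrophages carry too, with an adjusted p of up to 0.059 without control 1 or 4. The dendritic cell list did not pass (camera adjusted p = 0.0574; 0.0371 without imiquimod 1, 0.0473 without imiquimod 4, 0.0437 with an intensity trend and 0.045 with normexp at an offset of 16). None of 13 mast cell and eosinophil markers passed, with a mean of 0.01 (camera adjusted p = 0.65). Of these, Ccr3 and Tpsab1 had control means of 7.01 and 6.61, so a flat mean says little of such dim genes. For mast cell markers and for luminal epithelial markers fry gave the lower direction although the mean lay above 0. Ifng, Gzmb, Prf1 and Foxp3 were too dim to be tested.

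Genes of cell division were lower in all 4 imiquimod tumours. Of 26 proliferation genes, 18 fell and none rose (24 adjusted over the list alone), with a mean of -0.89 (camera adjusted p = 8.93e-25; adjusted p = 0.0608 with an estimated correlation). The scores per tumour lay between -1.004 and -0.738 with imiquimod and between -0.09 and 0.20 in controls (exact permutation test, p = 0.0286, the smallest possible). The mitotic kinase Plk1 fell by 1.59 (SE 0.16), the proliferation antigen Mki67 by 1.23 (SE 0.11), the replicative helicase subunit Mcm5 by 0.99 (SE 0.09) and the spindle factor Tpx2 by 0.94 (SE 0.07). A dimmer second probe of Plk1 gave -0.07 and that of Mki67 -0.06. Prc1, which organises the central spindle, fell by 1.55 (SE 0.14) and Cdca3 by 1.74 (SE 0.21). The replication-dependent histone H2A genes H2ac24, H2ac10, H2ac22, H2ac13, H2ac20 and H2ac12 had log2 fold changes from -1.76 to -1.62. Their sequences are near-identical, so it is uncertain how many separate genes changed. Ncald, a neuronal calcium sensor, fell by 1.51 (SE 0.22). Cyclin D1 (Ccnd1) fell by 1.60 (SE 0.34, adjusted p = 0.0349), a call lost without any control or without imiquimod 2 or 3 (adjusted p up to 0.0887), and its other probes gave -1.49 to -0.85.

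**Figure D2:**
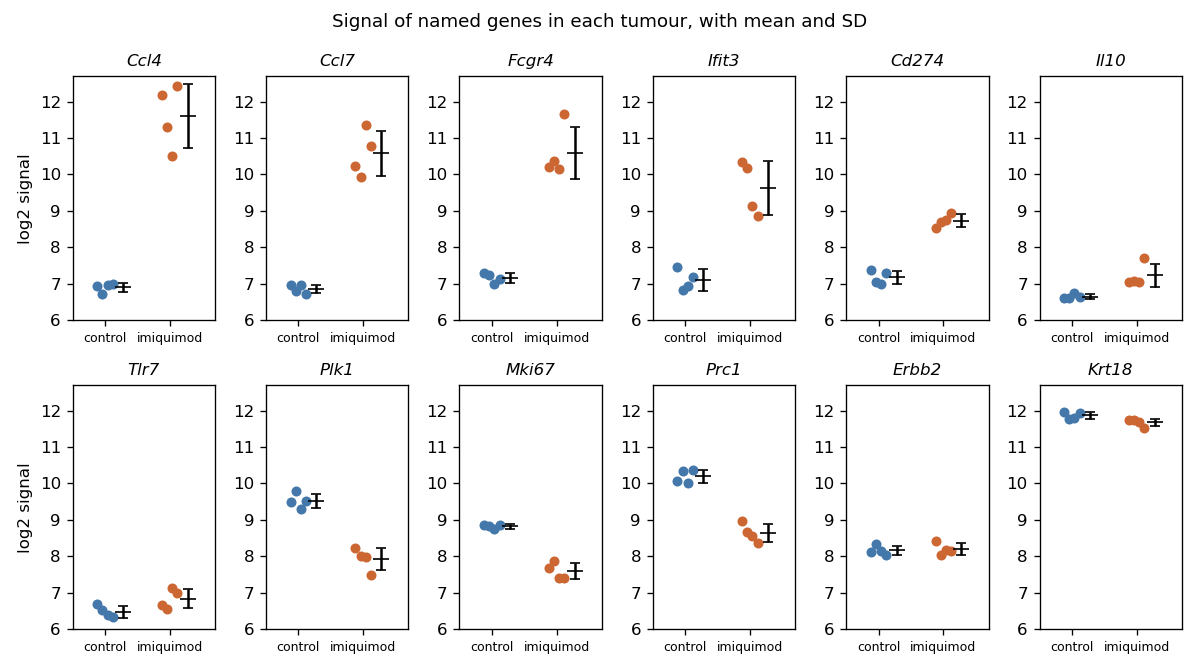
Log2 signal (y axis) of 12 genes in each of 4 control and 4 imiquimod tumours (points), with the group mean and SD (bars) beside them. The groups are apart for Ccl4, Plk1 and Prc1, and overlap for Tlr7 and Erbb2.

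The epithelial markers of the tumour did not pass as a list. Of 20 luminal and tumour cell markers, 1 rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.804). The member was Muc1 (1.14, adjusted p = 0.0486), with an adjusted p of up to 0.115 without any control or without imiquimod 3. The mouse Erbb2 probe had a log2 fold change of 0.02 (SE 0.10, adjusted p = 0.929). The neu transgene is the rat form of this gene, and whether the mouse probe reports it is unknown. Of 22 genes of ErbB signalling, 1 rose and 4 fell (1 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.188). Errfi1, a feedback inhibitor of ErbB receptors, rose by 0.95 (SE 0.14). The ligand Egf fell by 0.87 and the ERK phosphatase Dusp6 by 0.94. Egf lost its call without control 4 or imiquimod 2 or 4 (adjusted p up to 0.0594), and Dusp6 without control 1 or 3 (up to 0.0543).

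Of 27 oxidative phosphorylation genes, 3 fell and none rose (11 adjusted over the list alone), with a mean of -0.24 (camera adjusted p = 3.82e-05; adjusted p = 0.244 with an estimated correlation). Atp5o, a subunit of ATP synthase, fell by 0.58 (SE 0.09). Uqcrc1, of complex III, fell by 0.55. It lost its call without control 1 or imiquimod 2, 3 or 4 (adjusted p up to 0.0739). Of 24 hypoxia and glycolysis genes, 3 fell and none rose (6 adjusted over the list alone), with a mean of -0.37 (camera adjusted p = 0.000194; adjusted p = 0.252 with an estimated correlation). They were the glycolytic enzymes Tpi1 (-1.08), Pgk1 (-0.73) and Pfkl (-0.55), with adjusted p from 0.0404 to 0.0486. Tpi1 lost its call without control 1 or 3 or imiquimod 2, 3 or 4, Pgk1 without any tumour but control 4 and Pfkl without any but control 1 (adjusted p up to 0.122). A second probe of Tpi1 gave -0.07. None of 30 ribosomal protein genes passed (mean -0.08, camera adjusted p = 0.22), though the list reached 0.00397 without control 2.

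None of 27 apoptosis and p53 target genes passed, also adjusted over the list alone. Their mean was 0.13 (camera adjusted p = 0.0334; adjusted p = 0.19 with an estimated correlation), and the list had 0.0727 without control 3 and 0.0768 without imiquimod 3. Without imiquimod 3 and 4 together its mean was 0.09 (adjusted p = 0.121). Of 14 immediate-early and heat shock genes, 2 rose and none fell (4 adjusted over the list alone), with a mean of 0.36 (camera adjusted p = 0.00362; adjusted p = 0.278 with an estimated correlation). The scores were 0.21, 0.10, 0.60 and 0.54 in imiquimod 1 to 4, and without tumours 3 and 4, which carried the most skeletal muscle signal, the mean was 0.17 (adjusted p = 0.199). The genes that rose were the transcription factors Egr1 (1.06) and Junb (0.71). Egr1 lost its call without control 1, 3 or 4 or imiquimod 4 (adjusted p up to 0.0652), and Junb without control 1, 3 or 4 or imiquimod 1 or 3 (up to 0.0893).

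Markers of stroma and neighbouring tissue differed between the imiquimod tumours. Of 24 fibroblast and matrix genes, 2 rose and none fell (4 adjusted over the list alone), with a mean of 0.82 (camera adjusted p = 8.18e-08; adjusted p = 0.287 with an estimated correlation). The score was -0.09 in imiquimod 1, 0.88 in imiquimod 2 and 1.64 in imiquimod 3 (exact permutation test over all tumours, p = 0.0857). With fry the list did not pass (adjusted p = 0.11). Without tumours 3 and 4 the mean was 0.42, which imiquimod 2 carried, and the list still passed with camera at the preset correlation. The protease Mmp14 rose by 1.67, with an adjusted p of up to 0.0557 without control 1 or 3 or imiquimod 3. The proteoglycan Dcn rose by 2.35 (adjusted p = 0.0483), a call lost without any tumour but imiquimod 1 (up to 0.122), and its other probes gave 0.04 to 1.69. None of 19 endothelial markers passed, with a mean of 0.27 (camera adjusted p = 0.000252; adjusted p = 0.29 with an estimated correlation). The endothelial score was 0.48 and 0.54 in imiquimod 3 and 4 but 0.00 and 0.07 in imiquimod 1 and 2, and without tumours 3 and 4 the mean was 0.02 (adjusted p = 0.475). None of 17 adipocyte markers passed, with a mean of 0.46 (camera adjusted p = 0.00585; adjusted p = 0.29 with an estimated correlation; 0.0558 with the stricter filter). The adipocyte score was 0.98 and 0.78 in imiquimod 2 and 3 but 0.07 and 0.02 in imiquimod 1 and 4, below the 0.27 of control 4 (exact permutation test, p = 0.171), and without imiquimod 2 the mean was 0.30 (adjusted p = 0.0246). None of 16 skeletal muscle markers passed, with a mean of 0.68 (camera adjusted p = 0.000194; adjusted p = 0.344 with an estimated correlation). The muscle score was 1.60 in imiquimod 3 and 1.32 in imiquimod 4 but -0.06 and -0.14 in imiquimod 1 and 2, while control 1 had 0.41. The mean difference was 0.419 without imiquimod 3, 0.425 without imiquimod 4 and -0.12 without both.

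Of 12 basal and myoepithelial markers, 1 rose, also adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.167 with an estimated correlation). It was the keratin Krt14 (1.39, adjusted p = 0.0361), with an adjusted p of up to 0.0951 without any control or without imiquimod 1 or 3. Of 19 milk and secretory genes, 1 fell, also adjusted over the list alone, while the list's mean was 0.82 and did not pass (camera adjusted p = 0.0504). The member was transferrin (Trf, -0.55), a call lost without any tumour but imiquimod 1 (adjusted p up to 0.0951). The milk score was 2.18 in imiquimod 2 and -0.21 in imiquimod 1. Without imiquimod 2 the mean was 0.36 (adjusted p = 0.195), and the list's adjusted p lay between 0.00582 and 0.0407 without control 3 or 4 or imiquimod 1 or 4. It passed in 11 of 22 alternatives in all, among them several that kept all tumours, such as no filter on dim probes (0.0238) and the intensity trend (0.0373). None of 12 keratinocyte markers passed, with a mean of 0.17 (camera adjusted p = 0.119; 0.0473 without imiquimod 4 and 0.0048 without imiquimod 3 and 4 together) and a score of 0.58 in imiquimod 1, without which the mean was 0.04. None of 10 red blood cell genes passed, with a mean of -0.30 (camera adjusted p = 0.59), and -0.53 without imiquimod 3.

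**Figure D3:**
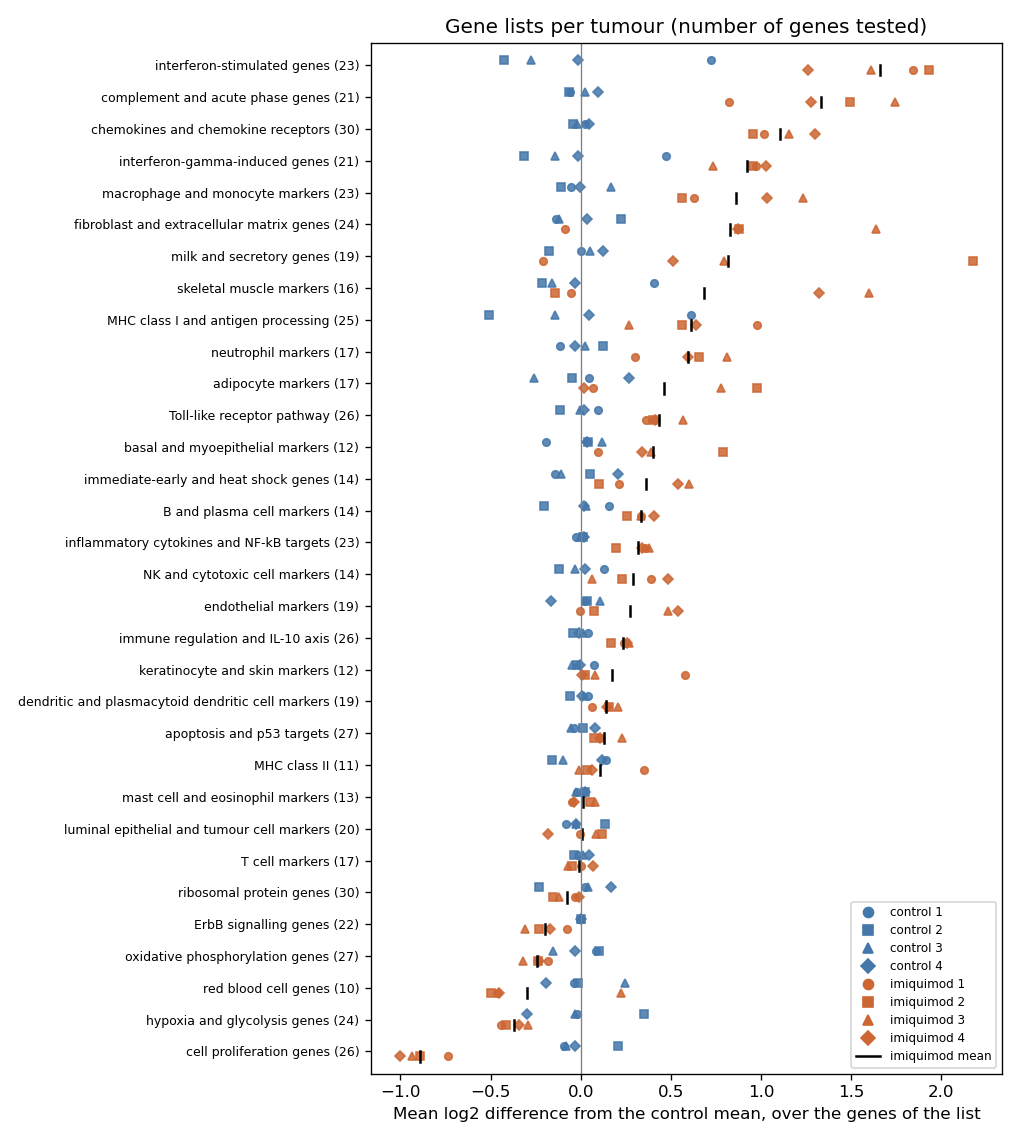
Mean log2 difference from the control mean over the genes of each list (x axis) in each of 4 control and 4 imiquimod tumours (points), with the imiquimod mean as a bar and the number of genes tested in brackets. Interferon-stimulated genes lie between 1.26 and 1.93 and proliferation genes between -1.004 and -0.738 in imiquimod tumours, while skeletal muscle markers are high in imiquimod 3 and 4 alone.

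In all, 21 of 32 lists passed with camera, 18 higher and 3 lower, 1 passed with an estimated correlation and 12 with fry, and other divisions of the same 8 arrays gave up to 20 lists. Those past fry's threshold were the chemokine, interferon-stimulated, interferon-gamma, Toll-like receptor, inflammatory, immune regulation, complement, macrophage, neutrophil, B cell, proliferation and oxidative phosphorylation lists. The scores of the groups did not overlap in 11 of the 21 lists that passed with camera. They overlapped in the other 10, which were MHC class I, NK, basal, fibroblast, endothelial, adipocyte, muscle, apoptosis, hypoxia and immediate-early genes. The count of 569 genes depended on the tumours: it was 308, 379 and 297 without control 1, 3 and 4, 913, 302, 279 and 314 without imiquimod 1, 2, 3 and 4, and 112 without imiquimod 3 and 4 together.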

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

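The test on genes of matched signal and both tests of oxidative phosphorylation genes were chosen only after the results were seen.

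Other divisions of the 8 arrays into 4 and 4 bear on the count of genes and less on that of lists. For genes, 1 of 35 divisions, the real one, gave as many as 569, and the highest of the others gave 2, so chance was excluded only as far as 35 divisions allow (2.86%). For lists, 1 of 35 gave as many as 21, but another gave 20, so a large number of lists past camera's threshold at the preset correlation does not by itself set the treatment apart.

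A tumour far from the other 3 of its group, by the gap to its nearest neighbour, was found in 21 of 284 groups of values checked over 110 genes and 32 lists, where chance gives about 5%. Imiquimod 4 was high for Fcgr4 (11.66, against 10.14 to 10.36 in the other imiquimod tumours), Il10 (7.72, against 7.05 to 7.09) and Itgax (7.42, against 6.96 to 6.98). Imiquimod 3 was high for the haemoglobin genes Hba-a1 (14.49, against 10.55 to 10.86) and Hbb-b2 (10.73, against 7.18 to 7.68), for the mean of red blood cell genes (0.22, against -0.50 to -0.45) and for Krt17 (7.92, against 6.91 to 7.001). Imiquimod 1 was high for Krt10 (8.79, against 7.28 to 7.36), for the mean of keratinocyte markers (0.58, against 0.01 to 0.08) and for Cd74 (10.20, against 9.12 to 9.29), and low for Dcn (8.44, against 10.29 to 10.54). Imiquimod 2 was low for Aif1 (9.01, against 9.91 to 9.95) and high for Prlr (8.77, against 8.33 to 8.36). Control 2 was high for Socs3 (7.62, against 6.94 to 6.99), Ltf (9.87, against 8.36 to 8.58), Lpl (7.68, against 7.53 to 7.55) and Mcm5 (10.09, against 9.81 to 9.85), and low for Nkg7 (6.50, against 6.88 to 6.94). Control 1 was high for Tap2 (10.35, against 10.15 to 10.17) and low for Mb (7.002, against 7.21 to 7.23), and control 4 was low for Fpr2 (6.25, against 6.56 to 6.62).

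The fall of proliferation genes was set against a lower share of epithelial cells. Luminal markers had a mean difference of 0.00 against -0.89 for proliferation genes, a gap of 0.90 per tumour (exact permutation test, p = 0.0286), which argues against that share as the whole cause. A distortion by the authors' normalization that depends on signal was looked for in 483 genes nearest in mean signal. They had a mean difference of 0.01, a gap of 0.90 (exact permutation test, p = 0.0286), so genes of that brightness did not fall in general. Equal distributions hold the mean of such genes near 0 whatever the normalization did, so this test cannot exclude a distortion. A shift of all transcripts could not be tested, since the equal distributions of the deposited values remove it. A hypothesis left open is that cells in the treated tumours may divide less, and which cells these would be was not measured.

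The rise of macrophage and chemokine genes was set against inflamed skin and blood taken with the tumour. Red blood cell genes had a mean of -0.30, lying 1.16 below the macrophage markers (difference -1.16, exact permutation test, p = 0.0286), which argues against blood. Keratinocyte markers had a mean of 0.17 against 0.86 (difference -0.69, exact permutation test, p = 0.0571), so skin cannot be told apart from a change in the tumour. The skin scores were 0.58, 0.02, 0.08 and 0.01 in imiquimod 1 to 4 and the macrophage scores 0.63, 0.56, 1.23 and 1.03. A response of the tumour to imiquimod may account for the rise and stays open too.

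The lower oxidative phosphorylation genes stay open. Luminal markers lay 0.25 above them (exact permutation test, p = 0.0571) and ribosomal genes 0.17 above them (p = 0.286, exact permutation test), so neither a lower epithelial share nor a loss of bright signal is excluded.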

How the results depend on the processing

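The normexp settings, the repeated quantile normalization and the joint removal of imiquimod 3 and 4 were chosen after seeing the data. No gene past the threshold changed sign under any alternative run, although 19 of 136 with several probes had a probe of the other sign. The 569 genes (280 higher, 289 lower) became 501 to 647 under the settings that kept all tumours and the threshold, 279 to 913 with each tumour left out in turn, and 112 without imiquimod 3 and 4, of which 106 were shared. The normalization and background settings started from deposited values whose distributions were already nearly equal. Counts near 569 were therefore likely there and do not test the authors' normalization. Fewer samples lower the power, and the cause of the rise to 913 without imiquimod 1 was not tested. Looser thresholds gave 2700 (unadjusted p) and 1189 (adjusted p below 0.10). Cyclic loess gave 322 higher and 216 lower (59.9% higher against 49.2%); the cause was not tested. With the replicate number as a block, 501 genes passed, 403 of them shared. The numbers do not pair the tumours: deviations of same-numbered tumours correlated at -0.021 to 0.035, and control 3 correlated best with imiquimod 4 (0.17).

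The 21 lists became 19 to 24 across settings with camera, but 1 with an estimated correlation and 12 with fry, as the first allows for the correlation within lists. Signs turned only for results that had not passed and for muscle. With the stricter filter on dim probes, T cell markers had 0.026 and mast cell markers -0.063. Without imiquimod 3 and 4, mast cell markers had -0.001, muscle markers -0.123 and Tnnt3 -0.101. With each tumour left out in turn, T cell markers ranged from -0.039 to 0.010, mast cell markers from -0.010 to 0.054, luminal markers from -0.033 to 0.066 and Erbb2 from -0.054 to 0.085. Of 76 named genes past the threshold, 51 kept it with each tumour left out and 25 lost it at least once; of 34 others, 12 gained it at least once. Not run were a slide or scan date block, as the files used give neither, and the settings that start from non-normalized signals. Without detection calls, signal over background is unknown for dim genes.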

Other observations

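The gene groups in this part and their tests were chosen after the data were seen. Gene families were formed from shared symbol stems. Each of 340 families with 6 or more tested genes was tested for an excess of higher and of lower genes with Fisher's exact test. Of 680 tests in all, 12 passed an adjusted p of 0.05. Fisher's test takes genes as independent, so these adjusted p-values may be too small where members of a family move together. Besides the Ccl chemokines (8 of 19 higher, adjusted p = 1.65e-06), the families with an excess of higher genes were the guanylate binding proteins Gbp (4 of 6, adjusted p = 0.000672), the interferon regulatory factors Irf (4 of 10, adjusted p = 0.00659), the Stat transcription factors (3 of 7, adjusted p = 0.0302), the galectin-named genes Lgals (3 of 9, adjusted p = 0.0418) and the Ras association family Rassf (3 of 9, adjusted p = 0.0418; a second probe of Rassf2 had the other sign). Lgals9, which encodes a galectin that binds the checkpoint receptor Tim-3, rose by 1.69 (SE 0.21), with probes from 0.35 to 1.69. Lgals3bp, a secreted glycoprotein, rose by 2.06 (SE 0.42), with an SD of 0.96 among the controls.

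Families with an excess of lower genes included the histone family H2ac (6 of 9, adjusted p = 3.09e-06), the kinesins Kif (5 of 25, adjusted p = 0.0263), the Cdca genes (3 of 7, adjusted p = 0.0302), the helicase subunits Mcm (3 of 8, adjusted p = 0.0389) and the centromere proteins Cenp (4 of 18, adjusted p = 0.0389). Members of one family can share sequence, so these counts may hold fewer separate genes. Kif23, a motor of cytokinesis, fell by 0.72 (SE 0.09) and Cenph by 0.48 (SE 0.06). Bcl2a1a, Bcl2a1b and Bcl2a1d, survival genes of leukocytes that are near-identical copies, had log2 fold changes of 1.76, 1.65 and 1.55.

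Fkbp5, a chaperone that glucocorticoids induce, rose by 1.65 (SE 0.24, adjusted p = 0.00942), and so did Tsc22d3 (0.73), Sgk1 (0.60) and Klf9 (0.53), which are known glucocorticoid targets. A second probe gave 0.01 for Tsc22d3 and 0.33 for Sgk1. The hypothesis of a glucocorticoid response, 1 of 2 hypotheses tested in this way, was tested on 18 other targets picked from general knowledge, of which 16 were tested here. Their values had not been looked at, except that Ddit4 (-0.24) also stands in the hypoxia and glycolysis list and so entered its mean. It was also known that none of these targets was among the genes past the threshold. Their mean difference was 0.40 (exact permutation test, p = 0.0286, the smallest possible), which is consistent with the hypothesis. It rested on few genes: 10 of the 16 were above 0, the median was 0.17, and without the 2 largest, Angptl4 (2.63, adjusted p = 0.0616) and Pdk4 (1.31, adjusted p = 0.0982), the mean was 0.18 (exact permutation test, p = 0.0571). Fatty acids and fasting also induce both of those genes, and no steroid was measured.

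Fdps, Dhcr7 and Hmgcs1, enzymes of cholesterol synthesis, fell by 1.01, 0.89 and 0.43, and Scap, which activates that pathway, fell by 0.48. The hypothesis that sterol synthesis genes fell as a group was tested the same way on 19 other genes, of which 16 were tested here. Their mean difference was -0.21, with 14 of 16 below 0 (exact permutation test, p = 0.0571), so a group fall stays undecided. Sqle came nearest, with a log2 fold change of -0.69 (adjusted p = 0.0628).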
